A study of Haloferax mediterranei with 6 samples.

How the data were processed

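Total RNA of Haloferax mediterranei DF50 and of its deoR2 deletion derivative was amplified, labelled with Cy3 or Cy5 and hybridised to dual-colour Agilent arrays, per the labels' protocols. Each of the 6 samples is 1 array holding a fructose channel and a buffer channel of 1 strain. Groups, replicate numbers and the dye of each channel were taken from the labels, which give 3 replicates per strain.

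The deposited scanner files were written by Agilent Feature Extraction 10.7.3.1, per the file headers. They hold mean spot intensity and median local background intensity in each channel, as scanned, per the file headers. Processed signals, background-subtracted, detrended and dye-normalized, and their log10 ratio of red over green are also in them, per the file headers. The deposited value table holds the authors' log2 ratio, 1 value per probe. Set against the scanner files' log10 ratio over 3875 gene probes, its columns had slopes of -3.33 to -3.31 where fructose was Cy3 and 3.33 where it was Cy5, with correlations of -0.999 to -0.985 and 0.997 to 0.998. Its scale is therefore log2 and its direction fructose over buffer. Its column medians lay between -0.024 and -0.00014. How its values were centred and how spots were combined is not given in the sources used here.

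Spot intensities were read with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50, on all spots. Ratios were normalized within each array by loess, with control spots and other non-gene spots at weight 0. Spots marked as non-uniform or as population outliers in either channel, 3.64% to 4.83% of gene spots per array, were left out, and the remaining spots of a probe were averaged. Every ratio was turned to fructose over buffer by the dyes in the labels. A probe was kept where at least 0.5 of its spots were well above background in either channel on at least 3 arrays, which kept 3863 of 3875 probes with 14 missing values. Copies of a probe on an array differed by a median SD of log2 0.033 to 0.063.

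Fructose responses and their difference were fitted in 1 limma model over all 6 arrays, with a term for each strain and a common dye term. Its 3 residual degrees of freedom were moderated with 4.75 prior ones. The dye term itself was past the threshold for 195 probes. Strain differences within a condition were fitted on single channels after loess and Aquantile normalization, with 4 strain and condition means, a dye term and an intraspot correlation of 0.712, over 3852 probes with no missing array. All p-values are two-sided and adjusted by the Benjamini-Hochberg method over the probes of a comparison, and calls are at an adjusted p under 0.05. Where a probe was not well above background on any array of a group, a bound is given in place of a fold. It sets the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own, on normalized log2 values. Dye swaps were unbalanced within a strain but the same in both strains. A dye effect common to them therefore cancels where a bound uses the probe's own signal, and only dye bias that differs between them stays open. Where a bound uses the lowest signal of other probes, the probe's own dye effect does not cancel.

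The rule for named probes took, for each fructose comparison, the 10 largest changes each way among called probes with the same sign on every array of the strain, or with no overlap between the strains' arrays for the difference. For strain comparisons it took the 5 largest each way. The files describe every gene probe as unknown, and the table of 3953 reference genes, 454 with a symbol, shares no identifier with them. At most a few of the probes chosen by the rule are therefore printed, and no gene name is given. The 25 gene lists fixed in advance, their camera tests, the description of genome neighbours and the lookup of deoR2 were not run for this reason. Runs were defined after the values were seen, as at least 2 consecutively numbered probes, all called, moving the same way and changed at least 2-fold in DF50. Smaller runs told of in the closing section had no limit of size for the difference and a limit of log2 0.5 for the deletion strain.

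Besides the gene probes, 8 probes with another naming pattern and 59 bases were left out of the tests and are described separately, as are 10 spike-in control probes. All 6 arrays were on 1 slide, in 2 rows: the first row held all DF50 arrays and deletion-strain replicate 1. No scan or slide batch separates the strains fully, and slide row was tried as a block.

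Replicate numbers are shared between the strains. Deviations of same-numbered arrays from their strain means correlated at 0.202, 0.606 and 0.478 for replicates 1, 2 and 3. Those of differently numbered arrays correlated at -0.587 to 0.199. The highest of these, DF50 replicate 3 with deletion-strain replicate 1, was close to the replicate 1 pair. The numbers were taken to pair the arrays, though this rests mostly on replicates 2 and 3. Replicate 2 is the array of opposite dye orientation in both strains, so part of these correlations is dye. The difference between replicates 1 and 3, which is free of dye, correlated between strains at 0.222. The replicate block was an alternative fit, so the main p-values do not take the pairing into account. The overlap of calls was also simulated, after the values were seen, with no response, normal errors at each probe's moderated SD, independent between probes, and paired arrays correlated at the dye-free or the highest value. The most extreme probes by t were then taken in lists as long as the real ones.

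The fits were tested on simulated data with 200 changed probes of known size. Errors were normal and independent between arrays, unlike those of the paired arrays above, and no change under log2 0.5 was tried. Calls within a strain had a median absolute log2 of 0.31, so most of them are smaller than the sizes tried. For the DF50 response, over 3863 probes, 100% of changes of log2 0.5 and 100% of those of log2 1.0 were recovered, with 14 false calls. For the deletion-strain response, over 3863 probes, 100% and 100% were recovered, with 8 false calls. For the difference, over 3863 probes, 92.0% of changes of log2 0.5 and 100% of those of log2 1.0 were recovered, with 7 false calls. For the strain comparison with buffer, over 3852 probes, the shares were 53.0% and 99.0%, with 5 false calls. For that with fructose, over 3852 probes, they were 64.0% and 97.0%, with 2 false calls.

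Alternatives fixed before the data were examined covered background correction, the scanner's processed ratios or signals, the deposited values, normalization within and between arrays, the filter on dim probes, the dye term, the samples in the fit, the replicate block, array weights, a 2-fold limit, each array left out, slide row and robust moderation. Added after seeing the data were the 8 other probes, the first slide row alone and the correlation without the run of 7. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.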

Results

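Transcript levels of the haloarchaeon Haloferax mediterranei were measured on 6 dual-colour Agilent oligonucleotide arrays. Strain DF50, the parent strain that the labels call wild type, and a DF50 derivative lacking deoR2 were each represented by 3 arrays. The gene name deoR2 belongs to the DeoR family of transcription regulators, many of which respond to sugars or sugar phosphates. On each array, RNA from a culture given fructose to 50 mM was set against RNA from a culture of the same strain given buffer alone. Cultures were grown at 37 °C to an OD600 of 1.5 before the addition and harvested after an incubation of 45, for which the labels state no unit. Fructose RNA carried Cy3 on replicates 1 and 3 of both strains and Cy5 on replicate 2, so each strain held both dye orientations. The comparisons ask which transcripts responded to fructose in each strain, whether the response depended on deoR2, and whether the strains differed in either condition.

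Each array held 15744 spots, of which 15128 belonged to 3875 gene probes of 60 bases, most of them printed in 4 copies. Median gene-probe intensity per array lay between 3986 and 5229 in the green channel and between 3760 and 6628 in the red channel, over median local backgrounds of 23.0 to 24.0 and 34.0 to 36.0. Between 97.2% and 99.8% of gene spots were well above background in a channel, and no gene spot was saturated. After turning every ratio to fructose over buffer, arrays of DF50 correlated across probes with Pearson r of 0.746 to 0.834, and arrays of the deletion strain with r of 0.504 to 0.723. The precision of every value is limited by the number of arrays, 3 per strain. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. This spread is pooled over both strains and moderated across probes, so it can be smaller than that of 1 strain. For the probe with the largest DF50 rise, the SD of the log2 ratio was 0.476 over the DF50 arrays and 0.029 over the deletion-strain arrays.

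The files pair no probe with a gene name, and the reference table shares no identifier with them. Few probes are therefore given by ID, and the others are described as runs of consecutively numbered probes. The named probes passed the rule fixed in advance. HFM87_1526 passed it too, but its loss of signal in the deletion strain was looked for after its values were seen.

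The probe of the deleted gene could not be looked up by name. Of all gene probes, 1 was well above background on all 6 channels of DF50 and on none of the 6 channels of the deletion strain, and 0 showed the opposite. This probe, HFM87_1526 (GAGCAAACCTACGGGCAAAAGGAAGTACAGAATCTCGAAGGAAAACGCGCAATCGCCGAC), had a normalized log2 intensity in DF50 of 9.85 ± 0.11 with buffer and 14.14 ± 0.22 with fructose (SD, n = 3). In DF50 it rose 20.1-fold with fructose (log2 4.33, SE 0.06, limma adjusted p = 8.8e-09). It was at least 5.87-fold lower in the deletion strain with buffer and at least 129.7-fold lower with fructose. The limma fit on single channels used its measured signals and not these bounds. It gave adjusted p = 3.8e-09 with buffer and 8.3e-14 with fructose. No fold with fructose is given for it within the deletion strain, where it was not well above background in either channel.

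Fructose changed a broad set of transcripts in DF50, with the 5 largest rises in 1 run of 7 consecutively numbered probes that ends with HFM87_1526. The 7 probes rose by log2 4.21 to 5.39, and each rose on 3 of 3 arrays. The largest rise was that of HFM87_1523 (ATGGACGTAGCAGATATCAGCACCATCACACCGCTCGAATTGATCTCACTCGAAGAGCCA), 42.0-fold (log2 5.39, SE 0.12, adjusted p = 3.4e-08), with a mean of 5.33 ± 0.48 over the arrays (SD, n = 3). Outside this run the largest rise was that of HFM87_437 (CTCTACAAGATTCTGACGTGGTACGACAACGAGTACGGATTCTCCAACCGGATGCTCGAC), 24.6-fold (log2 4.62, SE 0.10, adjusted p = 3.0e-08). The largest fall was that of HFM87_434 (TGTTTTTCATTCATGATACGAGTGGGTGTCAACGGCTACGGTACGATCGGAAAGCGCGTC), which lies 3 numbers away and was 4.87-fold lower (log2 -2.28, SE 0.16, adjusted p = 0.00010). HFM87_1473 (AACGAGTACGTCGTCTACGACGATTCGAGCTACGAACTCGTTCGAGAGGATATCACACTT) was also lower (log2 -1.73, SE 0.10, adjusted p = 2.9e-05).

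In all, limma called 1148 of 3863 probes at an adjusted p under 0.05, 577 higher and 571 lower. The split was 480 and 683 of 1163 with the scanner's processed log ratio, and 476 and 677 of 1153 with the deposited values. Most of these changes were small, with a median absolute log2 of 0.31. A change of at least 2-fold was reached by 45 probes, 36 higher and 9 lower, so that large changes were mostly rises. Of the 45 probes, 26 lay in 8 runs of consecutive numbers moving the same way. The 6 higher runs other than the run of 7 held 2 to 4 probes each and rose by log2 1.77 to 3.97. The single lower run held 4 probes, at log2 -1.81 to -1.36. Its falls were largest on DF50 replicate 3, at -3.32 to -1.93, against -1.38 to -1.03 on replicates 1 and 2. The count fell to 121 without DF50 replicate 2, its only array of that dye orientation, and to 707 without DF50 replicate 3. All DF50 arrays lay in 1 slide row, so an effect of row on this count could not be tested.

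In the deletion strain, HFM87_437 had the largest rise and HFM87_434 the largest fall. HFM87_437 rose 8.26-fold (log2 3.05, SE 0.10, adjusted p = 1.6e-06) and HFM87_434 was 2.43-fold lower (log2 -1.28, SE 0.16, adjusted p = 0.0043), each on 3 of 3 arrays. The 6 other probes of the run of 7 had log2 ratios of -0.11 to 0.18, and none passed the threshold (lowest adjusted p = 0.14). The 6 smaller runs that rose in DF50 also rose here, each of their 15 probes past the threshold, at log2 0.32 to 2.82. The 4 probes of the lower run stood at log2 -0.88 to -0.69, and 2 of them passed the threshold.

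Across all probes, 675 of 3863 passed the threshold in the deletion strain, 363 higher and 312 lower, with a median absolute log2 of 0.31. At least 2-fold changes were reached by 17 probes, 16 higher and 1 lower, and all 17 were also called in the same direction in DF50. This count depended on the arrays and on the terms of the fit. It was 155 without deletion-strain replicate 1, 31 without deletion-strain replicate 2, 361 without DF50 replicate 2, and 1149 with the replicate block. Slide row as a block left 71, and the first slide row alone gave 88. Both rest in effect on deletion-strain replicate 1, the only array of this strain in that row. HFM87_434 was no longer past the threshold without deletion-strain replicate 2 (log2 -1.30, adjusted p = 0.12) or with slide row as a block (log2 -1.54, adjusted p = 0.059), so its size held while its precision fell.

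**Figure D1:**
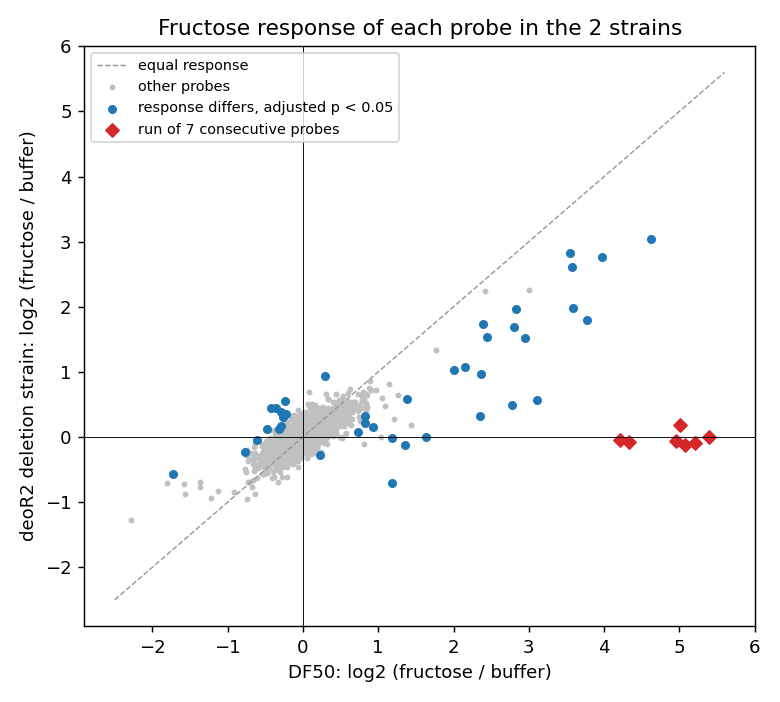
Each point is 1 probe, with its fitted log2 ratio of fructose over buffer in DF50 on the horizontal axis and in the deletion strain on the vertical axis. The 7 red diamonds stand at 4.21 to 5.39 in DF50 and at -0.11 to 0.18 in the deletion strain (for the seventh, HFM87_1526, not well above background there), and most blue points with large rises lie below the dashed line of equal response.

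The difference between the strains' responses was tested directly and centred on the same run. For its 6 probes measurable in both strains, the response was lower in the deletion strain by log2 -5.40 to -4.24 (median -5.10, largest adjusted p = 7.7e-07), and the 3 arrays of 1 strain did not overlap the 3 of the other. The difference was -5.40 for HFM87_1523 (SE 0.16) and -1.58 for HFM87_437 (SE 0.13, adjusted p = 0.00076), which rose in both strains. For HFM87_1473 it was 1.16 (SE 0.14, adjusted p = 0.0061), since the probe was at log2 -1.73 in DF50 and at -0.57 in the deletion strain. For HFM87_434 the difference of 1.00 did not pass (SE 0.22, adjusted p = 0.11), but it did with the replicate block (1.00, adjusted p = 0.0094) and without DF50 replicate 3 (1.28, adjusted p = 0.0065). Over its other alternatives the adjusted p was 0.058 to 0.58.

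In total 47 probes differed in response, 13 with a higher and 34 with a lower value in the deletion strain, and 1 of the 34 was HFM87_1526. Outside the run of 7, the 29 probes that rose at least 2-fold in DF50 all had smaller values in the deletion strain, and 22 of these differences passed the threshold. Of the 29, 24 were also called higher in the deletion strain and 16 reached 2-fold there. Among the 9 probes that fell at least 2-fold in DF50, all had smaller changes in the deletion strain, 7 were called lower there and 1 difference passed. The 9 include the 4 probes of the lower run, whose DF50 falls were largest on replicate 3. On the deletion-strain arrays these 4 read log2 -1.29 to -0.39, against -1.38 to -1.03 on DF50 replicates 1 and 2. Opposite calls in the 2 strains were made for 7 probes, all of them among the 47. Of the 7, 0 kept a call in both strains without replicate 2 of either strain or with slide row as a block. For the difference, leaving out replicate 2 of either strain gives the same fit, since the common dye term then takes up the other replicate 2. Only replicates 1 and 3 of both strains then inform it. The split into higher and lower values depended on the fit. It was 2 and 26 without replicate 2 of either strain, 0 and 18 with slide row as a block, 3 and 29 within the first slide row, and 41 and 46 with array weights. HFM87_1473 was no longer past the threshold with slide row as a block, at a difference of 1.25 (adjusted p = 0.11).

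Across probes, the strains' responses were correlated. The dye-balanced mean ratios correlated with Pearson r = 0.691 and Spearman rho = 0.774 over 3852 probes (covariance 0.0633), and with r = 0.833 without the run of 7. Probes are not independent replicates, so no p-value is attached. A correlation does not measure size, and most large responses outside the run were smaller in the deletion strain. Calls in both strains were shared by 242 higher and 245 lower probes, where independent lists of these sizes would share 54.2 and 46.1. Lists with shared error are not independent, since same-numbered arrays deviated together and the fit has a common dye term. In 50 simulations without any response, the top-ranked probes in lists of these sizes shared on average 113 and 98.5 at the dye-free correlation between paired arrays of 0.222. They shared 205 and 183 at the highest correlation of 0.606, which is partly dye, and at most 225 and 200. Such lists are ranks of noise, so they do not measure what part of the called overlap is shared array error. Some of it may be. The simulated Pearson r was 0.221 and 0.605 on average and at most 0.663, against the measured 0.691. The simulated data held only error, so their r repeats the correlation put in. Without the run of 7 the measured r was 0.833. This comparison therefore cannot decide how far the measured r reflects shared error. The simulated covariance was 0.0014 and 0.0037 on average and at most 0.0045, against the measured 0.0633, and the fits called 0.220 to 0.360 probes per strain on average.

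**Figure D2:**
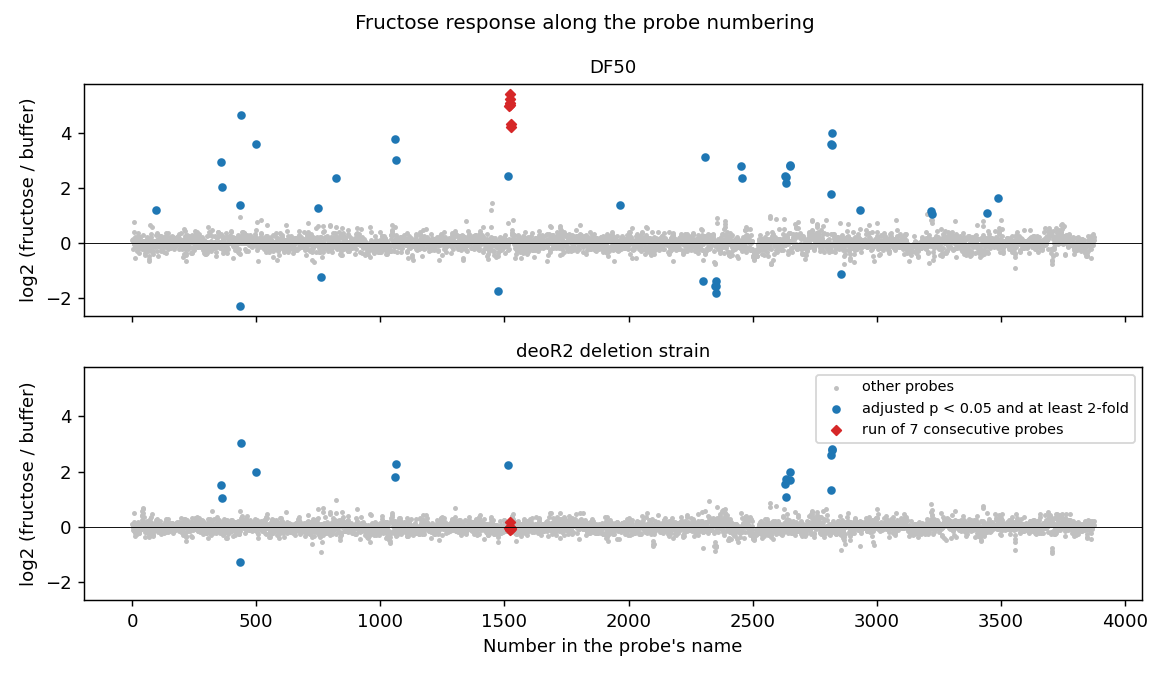
The fitted log2 ratio of fructose over buffer is plotted against the number in each probe's name, for DF50 above and the deletion strain below. The run of 7 (red) stands at 4.21 to 5.39 in DF50 and near 0 in the deletion strain (for the seventh, HFM87_1526, not well above background there). Several blue points at least 2-fold changed lie side by side in both strains.

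With buffer alone, the strains differed mainly in the same run. The 6 measurable probes were higher in the deletion strain by log2 1.98 to 3.62, or 3.93-fold to 12.3-fold (largest adjusted p = 5.9e-05). Their mean normalized log2 intensity was 11.27 ± 0.59 in DF50 and 14.28 ± 0.02 in the deletion strain (SD, n = 3). HFM87_1523 was 12.3-fold higher in the deletion strain (log2 3.62, SE 0.24, adjusted p = 2.9e-06). The channel-level fit called 8 of 3852 probes, 6 higher and 2 lower in the deletion strain, HFM87_1526 being 1 of the lower ones. The other lower probe belonged to the 4-probe run that rose with fructose in both strains, at log2 -0.77 (SE 0.12, adjusted p = 0.012). Its call was lost in 4 of 6 fits with 1 array left out, at log2 -0.82 to -0.71 over the 6, and with no normalization between arrays. The split was 6 higher and 1 lower with no normalization between arrays, and 6 and 4 with quantile normalization. Within the first slide row, with 1 deletion-strain array, 2 probes were called and HFM87_1523 was no longer past the threshold (adjusted p = 0.078), at 91.8% of its log2 value in the fit of all arrays.

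With fructose the order of the strains in this run was turned round. The 6 probes were lower in the deletion strain by log2 -2.30 to -1.78 (largest adjusted p = 0.0014), at a mean of 14.20 ± 0.06 against 16.18 ± 0.22 in DF50 (SD, n = 3). In the deletion strain their means with buffer and with fructose both lay above the DF50 buffer level and below the DF50 fructose level. HFM87_1523 was 3.42-fold lower in the deletion strain (log2 -1.78, SE 0.24, adjusted p = 0.0014) and HFM87_1473 was 2.15-fold higher (log2 1.10, SE 0.17, adjusted p = 0.0031).

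In this condition 39 of 3852 probes differed, 6 higher and 33 lower in the deletion strain, and 23 of the 33 were at least 2-fold lower. All 15 probes of the 6 smaller runs that rose with fructose were among those lower in the deletion strain. With no normalization between arrays the count was 24, 0 higher and 24 lower. It was 24 without DF50 replicate 1, 25 without deletion-strain replicate 2 and 7 within the first slide row. HFM87_1473 lost its call with no normalization between arrays (log2 1.09), without deletion-strain replicate 1 (1.01) or 2 (1.14) and within the first slide row (1.30). HFM87_1523 lost its call without DF50 replicate 1 (log2 -1.68, adjusted p = 0.061) and within the first slide row (log2 -1.78, adjusted p = 0.44).

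**Figure D3:**
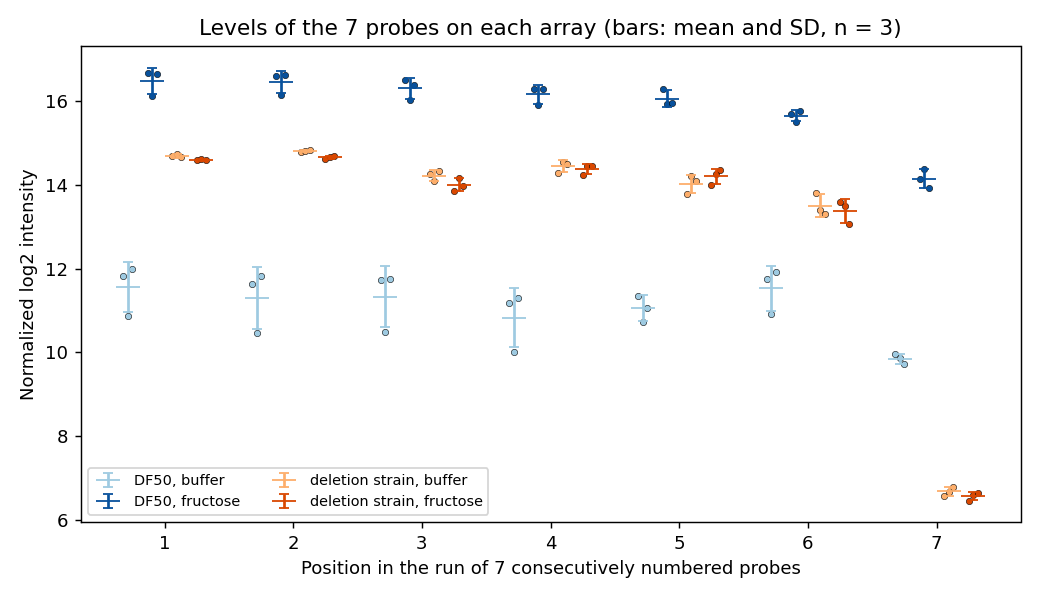
Normalized log2 intensity of the 7 consecutively numbered probes is shown by position in the run, with 1 point per array and the mean and SD of 3 arrays for each strain and condition. In positions 1 to 6 the deletion strain averages 14.28 with buffer and 14.20 with fructose, between the DF50 means of 11.27 and 16.18. At position 7, HFM87_1526, the deletion strain was not well above background.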

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

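The tests of the run and of the smaller responses in this part were chosen after the values had been seen, while the comparisons with other splits were fixed in advance.

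The response to fructose differed between the strains for 47 probes, by a direct test of the difference. The 10 ways of splitting the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 47 calls and the highest of the others 7, and 1 of the 10 splits, the real one, gave as many. Among the 4 splits that part every pair of same-numbered arrays, the highest other gave 0. For the response within a strain, 4 exchanges of the fructose and buffer channels are likewise too few. The real assignment gave 1148 calls in DF50 and 675 in the deletion strain, the others at most 0 and 0, so that 1 of 4 gave as many in each strain.

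The run of 6 consecutively numbered probes measurable in both strains had a median difference in response of log2 -5.10, and HFM87_1523 within it of -5.40. The probes rose in DF50 and passed no threshold in the deletion strain, where they stood at an intermediate level in both conditions. A signal ceiling is argued against by the gap between the strains with fructose, where DF50 read higher by at least log2 1.78 (SE 0.24) on each probe, and by 0 saturated spots. Deletion-strain cultures that had not received fructose are argued against by the 29 other probes that rose at least 2-fold in DF50, whose median log2 ratio in the deletion strain was 1.11 ± 0.08 (SD, n = 3). A raised buffer level made by normalization between arrays is argued against by a smallest difference of 1.94 (SE 0.19) without that normalization. A hypothesis that stays open is that the run depends on deoR2 for its low level with buffer and for its full rise with fructose. It was found and tested on the same arrays. HFM87_1526, which lost its signal in the deletion strain, ends the same run, and no array held that strain with deoR2 restored. Loss of deoR2 therefore cannot be told apart here from other effects of the deletion on this run.

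HFM87_437, which rose in both strains, had a difference of log2 -1.58, and it belongs to a wider pattern of smaller responses in the deletion strain outside the run. Compression of ratios on the deletion-strain arrays is argued against by the 10 spike-in control probes, whose slope of deletion-strain on DF50 ratios was 0.999 ± 0.051. With the 8 other probes, whose target is not known, the slope over 18 probes was 0.997 ± 0.052. That of 38 gene probes at least 2-fold changed in DF50 was 0.550 ± 0.053 (SD, n = 3 deletion-strain arrays for each slope). For rises, a choice of probes for large DF50 values is argued against by the 17 probes chosen for a 2-fold change in the deletion strain. Their median ratio of deletion-strain to DF50 response was 0.659 (SE 0.038 over probes), the highest ratio was 0.927 and 0 were above 1. The SE takes probes as independent, though 13 of the 17 lie in 5 runs of neighbours. Only 1 of the 17 fell, so this does not cover the falls. The place of the arrays on the slide cannot be told apart from the strain, since only 1 deletion-strain array shares the row of the DF50 arrays. Its slope was 0.554. A difference between the strains in how strongly or how fast they respond stays open and untested.

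HFM87_1473 had a positive difference, log2 1.16, since it was at log2 -1.73 in DF50 and fell less in the deletion strain. Its response was thus also smaller there. Among the 9 probes that fell at least 2-fold in DF50, it gave the 1 difference that passed. Its call was lost with slide row as a block.

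Signals were also present in probes outside the comparisons. The 8 probes with another naming pattern are in the deposited value table, and all 8 had the same sign of fructose over buffer on all 6 arrays, after turning for dye. The largest mean log2 ratio was 4.58, and their median GC content was 42.4%, against 51.7% for gene probes. The files do not say what they detect. The 10 spike-in control probes also kept 1 sign each on all 6 arrays, with means from log2 -1.08 to 2.46, so they followed the sample and not the dye.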

How the results depend on the processing

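The first-slide-row values and the correlation without the run of 7 were added after seeing the data. The run kept its calls widely: its 6 measurable probes were called in DF50, in the difference and with buffer under all alternatives fixed in advance and uncalled in the deletion strain, while with fructose 4 to 6 were called. Of 290 recomputed values of named probes, 278 kept direction and side of the threshold, 10 lost the call, 2 gained it and 0 reversed. Some could not move in size, since the filters on dim probes and robust moderation leave a probe's log2 unchanged. The probes were also chosen among the largest changes, so the tally does not stand for called probes in general. Requiring 2-fold left 45 probes in DF50, 17 in the deletion strain, 23 in the difference and 24 with fructose, by construction. For the other values the cause was not tested.

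Leaving out each array gave 121 to 1182 calls in DF50, 31 to 802 in the deletion strain, 28 to 43 in the difference, 7 to 8 with buffer and 24 to 40 with fructose. The deletion-strain count was 1038 with scaling between arrays, 415 with no dye term, 399 with that strain's arrays alone, 1037 with array weights, 71 with slide row as a block and 88 in the first slide row. With the replicate block it was 1149; the replicate block moved no other count by over 1.5 times and, among named probes, changed only the call of the HFM87_434 difference. The difference gave 87 with array weights and 18 with slide row as a block. The first slide row alone, with fewer arrays, gave 2 with buffer and 7 with fructose; with no normalization between arrays the latter was 24. The strains' correlation was 0.666 with median centring, 0.833 without the run of 7, and 0.665 to 0.700 with replicate 1 or 3 of a strain left out, replicate 2 being needed for the dye balance.

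The choice of the brightest probe per gene was not run, since the files do not say which probes share a gene, and the gene-list alternatives were not run, since probes are unnamed. Of the kept probes, 39 were not well above background on any deletion-strain array with buffer and 16 with fructose, against 0 and 0 in DF50, so their deletion-strain values are open to background. In both conditions it was 15, of which 0 were called there.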

Other observations

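The patterns here were noticed in the data; the tests of spot placement and shared sequence were set down before their results were seen.

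Some probes moved apart in the strains. Of the 7 probes called in opposite directions, 5 were lower in DF50 and higher in the deletion strain, and 2 the reverse. They include a run of 3 consecutive probes at log2 -0.36 to -0.27 in DF50 and 0.30 to 0.45 in the deletion strain (differences 0.57 to 0.81, largest adjusted p = 0.031). These calls were not stable: with slide row as a block 0 of the 7 differences passed, though those of the run of 3 kept their size at 0.58 to 0.81, and without replicate 2 of either strain 2 of the 7 and 0 of the run of 3 did, at 0.52 to 0.71. Leaving out either replicate 2 is the same fit of the difference, resting on replicates 1 and 3 of both strains. No limit of size was set for the run of 3, and one of log2 0.5 for the next 2 runs. In the deletion strain a run of 4 consecutive probes stood at log2 -0.69 to -0.51, and all 4 were also called lower in DF50, at -0.42 to -0.21. Another run of 3 rose with fructose in the deletion strain by log2 0.50 to 0.69, with 1 of the 3 called in DF50, at 0.06 to 0.30. These values are responses within a strain, and neither of these last runs was a run of called probes for the difference.

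Consecutively numbered probes responded alike. Leaving out the run of 7, the DF50 responses of 3842 consecutive pairs correlated with r = 0.366 and those of the deletion strain with r = 0.370. The highest of 10000 shuffles of the numbering, run on the DF50 responses alone, gave 0.082. The correlation was 0.170 for DF50 probes 2 numbers apart and 0.017 for those 5 apart. Probes next to each other on the array but not consecutive in number correlated at -0.0028 ± 0.0051, against 0.317 ± 0.021 for consecutive numbers (mean and SD over 3 DF50 arrays). These values were averaged over a probe's copies, which dilutes an effect shared by adjacent spots. They show only that averages of adjacent probes were not alike, and do not decide on placement of single spots. Shared probe sequence is argued against by a correlation of 0.316 ± 0.021 without the 21 pairs that share 12 bases. A hypothesis is that the numbers follow gene order and that neighbouring genes may be transcribed together, which was not tested here.

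The 26 probes in runs among those changed at least 2-fold in DF50 compare with a mean of 0.695 and at most 8 in 10000 shuffles of the numbering, and the longest shuffled run held 3 probes.

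The counts of strain differences within a condition did not stand apart from other splits of the 6 arrays. With 10 splits a share under 0.05 is out of reach, and 2 of the 10 gave as many calls, the real one included, in each condition. The real split gave 8 with buffer and 39 with fructose, and the highest other gave 24 and 59. That split also parts every pair of same-numbered arrays; it puts DF50 replicates 1 and 2 with deletion-strain replicate 3, the 3 arrays with the highest median red intensity, 5766 to 6628 against 3760 to 5350 in the rest. The link to red intensity was noticed after the counts were seen and was not tested, and the same split gave 0 calls for the difference in response. With the replicate block the real counts were 8 and 42.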
